A study of Mus musculus with 15 samples.

How the data were processed

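Small RNA libraries from C57BL/6 mouse pancreatic acini were analysed from the tables the authors deposited. Per the labels' protocols, total RNA was isolated with a mirVana kit and sequenced on an Illumina instrument. Per the submitters' processing notes, cutadapt and Bowtie were used with the builds GRCm38 and mm10; their versions and the counting tool are not given in the sources used here. The deposited table of mature miRNAs holds estimated counts (expected counts) that are already whole numbers: each value was within 0.5 of the sum, over the precursors of that miRNA, of the deposited table of estimated counts per precursor. Of the values above 0 per precursor, 74.0% were whole within 1e-06 and the others were fractional. Reads that fit several precursors may have been divided between them, which was not tested. Values of near-identical miRNAs such as the let-7 family may be uncertain to that extent. Another deposited table gives RPM, which matched the counts per precursor, scaled to the same total, within 0.0313. The RPM values served only for alternatives.

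Groups were taken from the sample titles. All 15 libraries entered 1 model of 5 group means in edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr (minimum count 10, minimum total 15), glmQLFit and glmQLFTest. This left 351 miRNAs, which held nearly all counts of each library, and 10 residual degrees of freedom. p-values were adjusted by Benjamini-Hochberg over the miRNAs tested, with a threshold of 0.05. There were 7 comparisons of group pairs and an F test over the 5 groups. CPM values are TMM-scaled, errors of levels are SD over 3 libraries, and the SE of a log2 fold change was derived from the F statistic. The median 95% interval reached 0.73 to either side of the log2 difference of caerulein 100 nM and control, and the biological coefficient of variation was 0.285. Totals ranged from 535473 to 5087728 counts; intervals from counts cover counting error only, since reads were not tagged by molecule.

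The comparisons, their tests, the alternatives, 14 miRNA lists and the rule for named miRNAs were fixed before the data were examined. Most tests of explanations for flagged results and of other observations were chosen afterwards, as stated with them. The lists were pancreatic acinar, islet and neuroendocrine, epithelial miR-200 family, mesenchymal, endothelial, leukocyte, erythrocyte, inflammation induced, calcium and CREB induced, p53 and stress, let-7 family, miR-17-92 cluster, miR-29 and miR-30 families, and liver and muscle. The rule named both arms of miR-21, up to 12 called miRNAs per direction with the smallest p, the 10 smallest unadjusted p-values where fewer than 6 miRNAs passed, the 5 most abundant miRNAs and up to 4 abundant members of each list; of these, some are given in the text and the others are summarised by list. Outside the rule, miR-155-5p, miR-17-3p, miR-217-3p, miR-148a-5p and miR-30c-5p were named as list members after their values were seen. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 78 tests. The arm ratio of miR-21 was log2 of 3p over 5p counts after adding 0.5 to each, tested with an exact permutation test.

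Alternatives were other scalings (RLE, upper quartile, library totals), removal of the 3 most abundant miRNAs, no filter or a mean CPM of at least 10, DESeq2 1.42.0, robust dispersion, limma on log2 RPM with a pseudocount of 1 or 10, a replicate block, the highest precursor row, the 2 groups alone, and leaving out each library or replicate number. Replicate pairs within groups differed by far more than sampling noise (chi-square per degree of freedom from 62.9 to 1852), so no library was treated as deposited more than once. With library totals in place of TMM the median log2 difference shifted by -0.24 for caerulein 100 pM, 0.10 for TLC-S 62.5 uM and 0.29 between the caerulein doses, and other scalings shifted it by less than 0.1. List medians and single differences smaller than these shifts carry no direction. Fold changes from limma on log2 RPM with a pseudocount understate changes of scarce miRNAs.

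The model was tested on simulated counts with the mean levels of the control group and the dispersions and depths of these libraries. The counts were drawn independently for each miRNA and without differences between replicate numbers, so the rates may be better than in the data. For TLC-S 62.5 uM against control, with 20 of 351 miRNAs changed, the model recovered 35.7% of 2-fold, 81.4% of 4-fold and 91.7% of 8-fold changes, and 6.80% of calls were false. With 200 changed it recovered 59.0%, 92.7% and 98.5%. For caerulein 100 nM against control with 20 changed, recovery was 38.6%, 82.9% and 95.0%. Precursors were placed on GRCm38 with GENCODE M21, in which 1979 of 2061 precursor rows matched. Python 3.11.15 and matplotlib 3.10.9 drew the figures.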

Results

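Small RNA was sequenced from mouse pancreatic acini, the clusters of exocrine cells that make and secrete digestive enzymes. The 15 libraries formed 5 groups of 3: untreated control, caerulein at 100 nM, caerulein at 100 pM, and taurolithocholic acid 3-sulfate (TLC-S) at 250 uM and at 62.5 uM. Caerulein is a peptide agonist of the cholecystokinin receptor, and the labels call its higher dose pathological and its lower dose physiological. TLC-S is a bile acid used to injure acinar cells. The series title names the 3p arm of miR-21 as over-expressed in acute pancreatitis, so both arms of that hairpin were examined in each comparison. The extract protocol speaks of pooled RNA from independent acinar preparations without saying which library holds which, so p-values measure only the spread between these libraries, which may be technical.

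Total miRNA counts ran from 535473 in replicate 2 of caerulein 100 nM to 5087728 in replicate 3 of that group. Of 1915 mature miRNAs in the table, 867 had a count in at least 1 library and 351 passed the low-count filter and were tested. The most abundant miRNAs included members of the acinar list (miR-148a-3p and miR-217-5p), of the islet and neuroendocrine list (miR-375-3p) and of the epithelial miR-200 family. miR-148a-3p held 27.9% ± 9.43 of counts (SD, n = 15), miR-375-3p 10.1% ± 2.23, miR-217-5p 8.84% ± 2.06 and miR-200a-3p 4.24% ± 1.29. The acinar list together held 39.0% of counts and the islet and neuroendocrine list 11.6%, most of it miR-375-3p. The share of miR-148a-3p was 50.5% in control replicate 3 and 17.6% and 18.7% in the other control libraries. In GRCm38, Mir148a lies on chromosome 6 from 51269812 to 51269910 outside annotated genes, Mir375 on chromosome 1 from 74900658 to 74900721 outside annotated genes, and Mir217 on chromosome 11 from 28763728 to 28763835 in an intron of Gm12082. None of the most abundant 5 miRNAs passed the test in any of the 7 comparisons of group pairs made with edgeR's quasi-likelihood test.

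The comparison of the pathological caerulein dose with control addressed which miRNAs respond to supramaximal stimulation. With caerulein at 100 nM, miR-21a-3p was at 13.6 ± 11.4 CPM (TMM-scaled CPM, SD, n = 3) against 3.11 ± 1.95 in control. The log2 difference was 2.18 with an SE of 0.71 and a 95% interval from 0.73 to 3.64, and it did not pass over all miRNAs tested (adjusted p = 0.432, edgeR). The other arm of the hairpin, miR-21a-5p, was at 19933 ± 5004 CPM against 20109 ± 2816, a log2 difference of -0.01 with an interval from -0.55 to 0.53. The raw 3p counts were 6, 7 and 136 with caerulein at 100 nM and 3, 7 and 11 in control. At the depths of the treated libraries these were 2.94, 12.2 and 25.6 CPM, against at most 5.26 in control, so 2 of 3 treated libraries lay above every control. Without replicate 3 of caerulein 100 nM, the deepest library, the difference was 1.00 with an SE of 0.89, and without replicate 1 it was 2.70 with an SE of 0.69. Mir21a lies on chromosome 11 from 86584067 to 86584158 on the minus strand, within an exon of Vmp1.

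In total 0 of 351 miRNAs passed at an adjusted p under 0.05 in this comparison with edgeR, against 12 at an unadjusted p under 0.05 and 1 adjusted call by DESeq2, miR-3968. The smallest p in edgeR belonged to miR-3968, at 78.1 ± 13.2 CPM against 38.4 ± 4.71 (log2 difference 1.04, SE 0.28, adjusted p = 0.343), which was higher in 3 of 3 libraries than in any control. Next were miR-126a-5p (log2 difference -0.90, SE 0.28), miR-6240 (1.46, SE 0.45), miR-21a-3p as given above and miR-126a-3p (-0.71, SE 0.28), none of which passed. miR-29a-5p, miR-411-5p, miR-221-5p, miR-382-3p and miR-433-3p also had small unadjusted p-values, with log2 differences of 1.49, -1.09, -1.36, -1.76 and -2.05. Groups did not overlap for 6.55% of miRNAs, where chance gives 10%.

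Among the lists fixed beforehand, both arms of miR-126a, which is made from a hairpin in Egfl7 and marks endothelial cells, passed when adjusted over the list alone (2 of 2) and not over all miRNAs tested (0 of 2). Leukocyte miRNAs were lower in 4 of 4 members with a median log2 difference of -0.40, and 0 passed (list test adjusted p = 0.176). In the inflammation list 4 of 7 members were positive, and only miR-21a-3p passed when adjusted over the list alone (0.034); the series title names that miRNA, so it may have been chosen on these samples, and its call is not taken as independent evidence. The other members included miR-155-5p at 0.65 with an SE of 0.76 and miR-146a-5p at 0.15 with an SE of 0.32. Acinar miRNAs had a median of 0.03 with 4 of 8 members positive, mesenchymal miRNAs a median of -0.11 with 6 of 8 negative, and 0 members of either list passed.

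**Figure D1:**
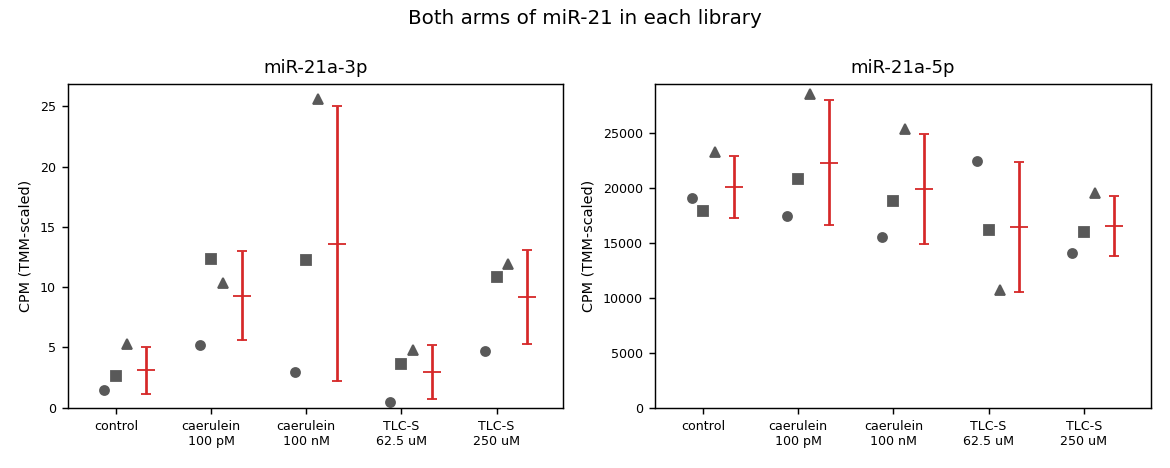
CPM of both arms of miR-21 (y axes, linear) in each library of the 5 groups (x axes). Circles, squares and triangles are replicates 1, 2 and 3, and red bars give mean ± SD; 1 library of caerulein 100 nM stands at 25.6 CPM of the 3p arm, and the 5p panel shows no separation of the groups.

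The physiological caerulein dose was compared with control in the same way. At 100 pM, miR-21a-3p was at 9.27 ± 3.69 CPM, a log2 difference of 1.55 with an SE of 0.74 (adjusted p = 0.722, edgeR), and miR-21a-5p differed by 0.15 with an SE of 0.26. Again 0 of 351 miRNAs passed with edgeR and 0 with DESeq2, against 24 at an unadjusted p under 0.05 with edgeR, 18 of them higher. miR-6240 (log2 difference 1.58, SE 0.46), miR-154-5p (-3.02, SE 0.89), miR-1957a (1.55, SE 0.53), miR-182-5p (0.74, SE 0.27) and miR-3968 (0.74, SE 0.28) had the smallest p-values. The miR-17-92 cluster, a polycistron linked to proliferation, was the only list called here. All 7 of its tested members were negative, with a median of -0.38, miR-17-3p at -1.24 and miR-19b-3p at -0.38; the preset-correlation test gave an adjusted p = 0.036, and the call was lost with an estimated correlation (adjusted p = 0.581). It was also lost without replicate 2 of every group (adjusted p = 0.912). The inflammation list had 6 of 7 members positive and a median of 0.45 (adjusted p = 0.194). Calcium and CREB induced miRNAs, chosen because caerulein raises cytosolic calcium, had a median of -0.60 with 1 of 3 members positive and 0 called.

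TLC-S at 250 uM was compared with control to ask which miRNAs respond to the bile acid at its higher dose. miR-21a-3p was at 9.16 ± 3.88 CPM, a log2 difference of 1.58 with an SE of 0.72 (adjusted p = 0.999, edgeR), and miR-21a-5p differed by -0.28 with an SE of 0.26. With edgeR 0 of 351 miRNAs passed and 4 had an unadjusted p under 0.05, and DESeq2 called 0. These 4 were miR-133a-3p (log2 difference 2.40, SE 0.81), miR-6240 (1.25, SE 0.45), miR-21a-3p and miR-1957a (1.11, SE 0.53), all higher. miR-133a-3p is a muscle miRNA from a list of tissues that were not sampled, and it passed when adjusted over the list alone (0.0271). The list of acinar miRNAs had a median of -0.10 with 6 of 8 members negative, and the miR-200 family of epithelial miRNAs a median of -0.18 with 5 of 7 negative; 0 members of either passed.

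With edgeR, the lower TLC-S dose gave the only calls against control; DESeq2 also called miR-3968 with caerulein at 100 nM. At 62.5 uM, miR-3968 fell to 11.2 ± 0.743 CPM from 38.4 ± 4.71 in control, a log2 difference of -1.77 with an SE of 0.30 (adjusted p = 0.00152, edgeR), lower in 3 of 3 libraries. miR-30b-5p, a member of the miR-30 family, fell to 805 ± 215 CPM from 2251 ± 1415, a log2 difference of -1.48 with an SE of 0.32 (adjusted p = 0.0191), also lower in 3 of 3 libraries. Mir3968 lies on chromosome 11 from 115447961 to 115448060 on the minus strand, opposite an exon of Trim80, and Mir30b on chromosome 15 from 68337415 to 68337510 within an exon of Gm26621. The remaining miRNAs did not pass in this edgeR model. Among them were miR-190a-5p (-1.47, SE 0.41), miR-335-5p (2.27, SE 0.64), miR-542-3p (1.34, SE 0.40), miR-216a-3p (-0.96, SE 0.29), miR-146a-5p (1.00, SE 0.32) and miR-184-3p (0.95, SE 0.31). Here miR-21a-3p was at 2.97 ± 2.24 CPM, a log2 difference of -0.10 with an interval from -1.74 to 1.54. The count of 2 rose to 4 with DESeq2, which added miR-190a-5p and miR-335-5p, and to 5 without the low-count filter, which added these and miR-146a-5p, and fell to 0 in a fit of the 6 libraries alone. The call of miR-30b-5p ended without control replicate 3 (log2 difference -0.82, adjusted p = 0.416), TLC-S 62.5 uM replicate 1 (adjusted p = 0.141) or TLC-S 62.5 uM replicate 3 (adjusted p = 0.0723), within a range from 2.18e-05 to 0.416 over its alternatives, and each of these left 1 call.

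Acinar miRNAs were lower as a group at 62.5 uM. All 8 tested members were negative, with a median log2 difference of -0.51, among them miR-216a-3p at -0.96, miR-217-3p at -0.66, miR-148a-5p at -0.55 and miR-217-5p at -0.17 (list test adjusted p = 0.00206). The members are not independent: they are arm pairs of the miR-216a, miR-216b, miR-217 and miR-148a hairpins, and Mir216a and Mir217 share 1 genomic cluster. The list call was lost with an estimated correlation of 0.176 in place of the preset 0.01 (adjusted p = 0.558). It was also lost without replicate 2 of every group (adjusted p = 0.545) or replicate 3 of every group (adjusted p = 0.135). Without control replicate 3, miR-148a-3p turned from -0.51 to 0.60. Only 1 member, miR-216a-3p, passed when adjusted over the list alone (0.0234), and 0 over all miRNAs tested. Beside this, both endothelial arms were lower (median -0.50), mesenchymal miRNAs were positive in 7 of 8 members (median 0.13), islet miRNAs had a median of -0.26, leukocyte miRNAs -0.14 and erythrocyte miRNAs 0.21. None of these lists was called, except that the endothelial list, with 2 members, had no list test. When adjusted over the list alone, 1 islet member passed, miR-184-3p (0.0365), and 1 of the inflammation list, miR-146a-5p (0.0339). In the miR-29 and miR-30 list miR-30b-5p was the 1 member of 8 that passed; the median was 0.08 and the mean -0.10, and the list was not called (adjusted p = 0.878). Among the others, miR-30a-5p was at 0.42 with an SE of 0.21, miR-30d-5p at 0.32 with an SE of 0.22 and miR-30c-5p at -0.37 with an SE of 0.23. The p53 and stress list had 6 of 6 members negative (median -0.11) and the let-7 family 6 of 9 negative (median -0.10), with 0 called. In the list of liver and muscle miRNAs, 2 of 4 passed when adjusted over the list alone, miR-133a-3p at 1.99 and miR-1a-3p at 1.20. That list is of tissues that were not sampled and held a mean of only 0.0044% of counts. Adjustment over a list alone does not correct for the number of lists or of comparisons. Passing in this way is therefore weak evidence of a response, for these 2 miRNAs and for every other miRNA reported to pass over its list alone.

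The 2 TLC-S doses were compared directly. miR-3968 was higher at 250 uM, at 36.5 ± 5.57 CPM against 11.2 ± 0.743 (log2 difference 1.69, SE 0.31, adjusted p = 0.00345, edgeR), and so was miR-30b-5p, at 2122 ± 368 against 805 ± 215 (1.40, SE 0.32, adjusted p = 0.0368). miR-203-3p, an epithelial miRNA, was lower at 250 uM, at 565 ± 42.2 CPM against 1095 ± 318 (-0.96, SE 0.24, adjusted p = 0.0449). miR-335-5p, from an intron of the imprinted gene Mest, was lower at 250 uM, at 3.54 ± 1.46 CPM against 23.6 ± 4.19 (-2.71, SE 0.68, adjusted p = 0.0449). Mir203 lies on chromosome 12 from 112130880 to 112130955 and Mir335 on chromosome 6 from 30741299 to 30741396. The call of miR-203-3p held in 4 of 31 alternative settings, that of miR-335-5p in 11 of 30 and that of miR-3968 in 28 of 31. These settings include leaving out control or caerulein libraries, which are in neither group compared. The call of miR-3968 was lost with limma at a pseudocount of 10 and without replicate 1 or replicate 2 of every group. Leaving out any 1 TLC-S library ended the calls of miR-203-3p (adjusted p up to 0.587, without TLC-S 62.5 uM replicate 1) and miR-335-5p (up to 0.330, without TLC-S 250 uM replicate 3). Over all alternatives the log2 difference ran from -1.09 to -0.60 for miR-203-3p and from -2.86 to -1.39 for miR-335-5p. The call of miR-30b-5p ended without any 1 library of TLC-S 250 uM, replicate 1 or 3 of TLC-S 62.5 uM, or replicate 1 or 2 of caerulein 100 nM, each of which left 1 call. Its log2 difference ran from 1.17 to 1.70 over 31 alternatives. DESeq2 also called 4 miRNAs, all of them among those called by edgeR. The acinar list, again arm pairs of few hairpins, was higher at 250 uM in 8 of 8 members (median 0.37, list test adjusted p = 0.0167). That call was lost with an estimated correlation (adjusted p = 0.558) and without replicate 2 of every group (adjusted p = 0.855) or replicate 3 of every group (adjusted p = 0.135).

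**Figure D2:**
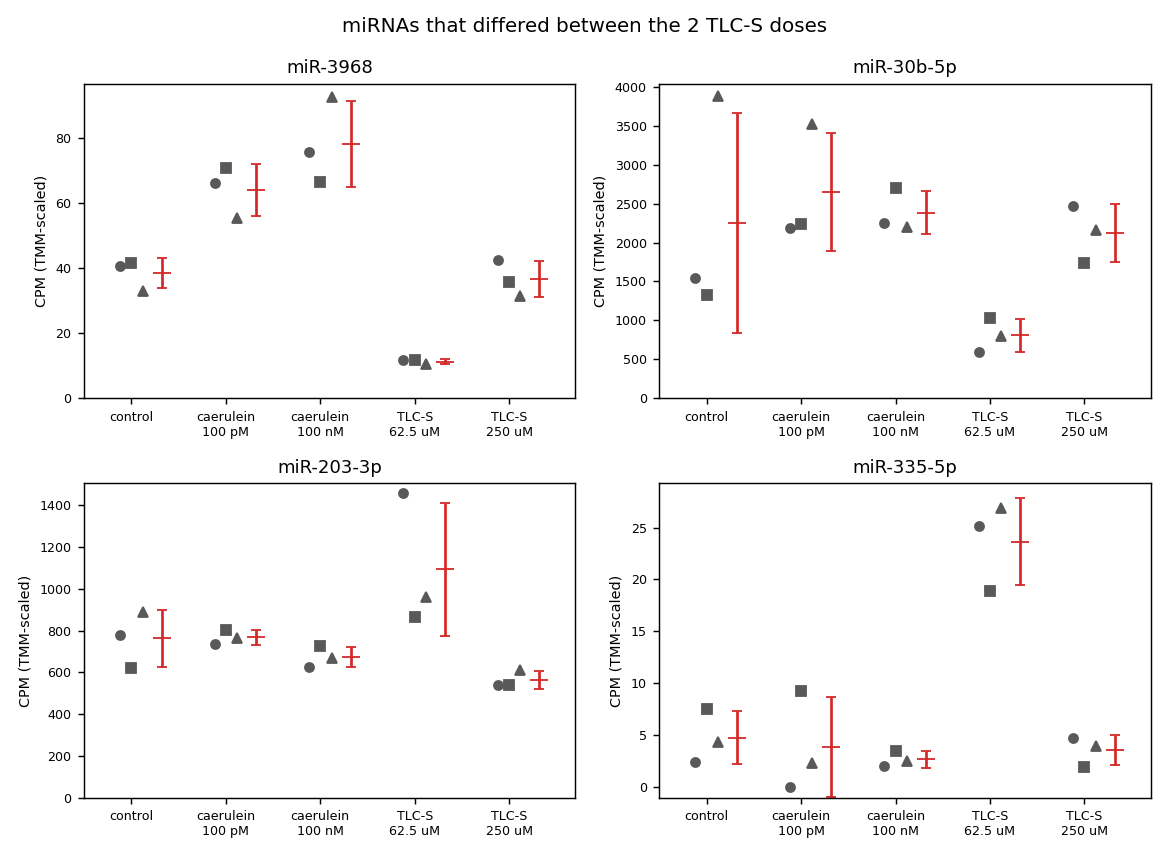
CPM (y axes, linear) of the 4 miRNAs that differed between the TLC-S doses, in each library of the 5 groups (x axes). Circles, squares and triangles are replicates 1, 2 and 3, and red bars give mean ± SD; miR-3968 lies near 11.2 CPM in the 3 libraries of TLC-S 62.5 uM, below every other library.

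Between the caerulein doses 0 of 351 miRNAs passed with edgeR and 0 with DESeq2, against 6 at an unadjusted p under 0.05 with edgeR. miR-154-5p was higher at 100 nM by 2.75 with an SE of 0.91, and miR-148a-3p differed by -0.85 with an SE of 0.41. miR-21a-3p differed by 0.64 with an interval from -0.74 to 2.02, so a difference between the doses was not detectable with these libraries. Between caerulein at 100 nM and TLC-S at 250 uM, 0 miRNAs passed with edgeR, 8 had an unadjusted p under 0.05 and DESeq2 called 1, miR-3968 (log2 difference 1.12, SE 0.28 in edgeR). The F test over all 5 groups called 3 miRNAs: miR-3968 (adjusted p = 1.17e-05, edgeR), miR-335-5p (0.0202) and miR-30b-5p (0.0344), against 26 at an unadjusted p under 0.05 and 7 calls by DESeq2. Without the low-count filter this test called 10 miRNAs, miR-21a-3p among them. It called 1, miR-3968, at a mean CPM of at least 10 or without any 1 of these libraries: caerulein 100 nM replicate 1 or 2, TLC-S 250 uM replicate 2 or 3, or any replicate of TLC-S 62.5 uM. Without caerulein 100 pM replicate 3 it called 2, and miR-30b-5p was lost.

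The ratio of the arms of miR-21 does not depend on scaling between libraries. The mean log2 ratio of 3p to 5p counts was -12.7 ± 0.710 in control (SD, n = 3). It was higher by 1.82 with caerulein at 100 nM (exact two-sided permutation p = 0.2), by 1.48 at 100 pM (exact p = 0.1) and by 1.86 with TLC-S at 250 uM (exact p = 0.1). With TLC-S at 62.5 uM it differed by 0.05 (exact p = 1). The smallest p that 3 against 3 allows is 0.1, so no difference could pass. Adjusted over the 4 comparisons with control alone, the edgeR p for miR-21a-3p was 0.0197, 0.0625, 0.0625 and 0.901 in the order caerulein 100 nM, caerulein 100 pM, TLC-S 250 uM and TLC-S 62.5 uM, with the same reservation that the series title names this miRNA. The value of 0.0197 also rested on replicate 3 of caerulein 100 nM, without which the log2 difference was 1.00 with an SE of 0.89.

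The changes of caerulein 100 nM and TLC-S 250 uM from control correlated across the 351 miRNAs (r = 0.567), which are not independent replicates. Simulations of unchanged groups drew new counts for all 15 libraries, with both groups set against the same 3 simulated controls. They gave a mean of 0.480, with 95% of simulations from 0.360 to 0.593. The miRNAs were drawn independently and without differences between replicate numbers. The covariance was 0.104 against a simulated 0.0972 (0.0691 to 0.132). Both observed values lay within the range that unchanged groups gave. No calls were shared, since neither comparison had one with edgeR, and with 3 control libraries the controls could not be split, so the correlation may come from the shared controls.

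**Figure D3:**
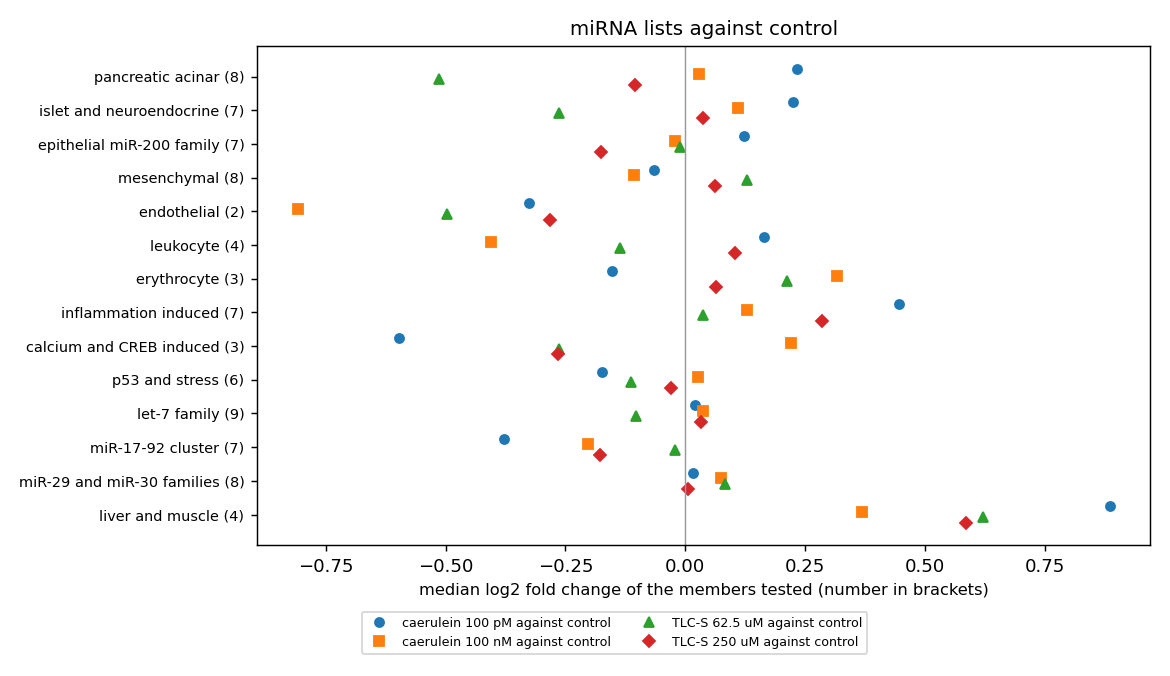
Median log2 fold change against control (x axis) of the tested members of each of the 14 miRNA lists (y axis, number of members in brackets) for the 4 treatments, 1 symbol per treatment. The acinar list lies at -0.51 for TLC-S 62.5 uM and the endothelial list at -0.81 for caerulein 100 nM.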

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

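Chosen only after the results were seen were the tests of scaling, the comparison with miRNAs of similar hairpin GC, the tests of counting noise and of 1 library for miR-21a-3p, and the test of the acinar share. The test of minor arms was set beforehand, but the limit used for it was not. The splits were set beforehand. The limits of 4 tests were replaced once their values were known. For 1 library the limit was first 1 SE, for counting noise it first rested on all libraries, and for the acinar share it was first 2 SE; these first limits would have counted against all 3 explanations. For minor arms the limit set beforehand was the lower end of the interval of miR-21, which came to 0.044, and the value found would have counted for that explanation. That limit was replaced because an explanation of the whole difference needs a rise of that size. For hairpin GC the removal of a linear trend had been set beforehand, and it decides nothing, since there was almost no trend to remove (rho = 0.049 across miRNAs).

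The change from control differed between the 2 TLC-S doses for 4 miRNAs, as tested by the contrast of the doses: miR-3968 by 1.69, miR-30b-5p by 1.40, miR-203-3p by -0.96 and miR-335-5p by -2.71 on the log2 scale (250 uM minus 62.5 uM). That 4 were called was the most of any split of these 6 libraries, the others calling at most 0, but 10 splits are too few for a share under 0.05 (1 of 10 reached the real count). For TLC-S 62.5 uM against control 2 were called and another split also called 2 (2 of 10), again too few splits. In the comparisons with 0 calls every split reaches the real count by definition (10 of 10), so the splits decide nothing there. The highest other count was 0 for caerulein 100 nM against control, 2 for caerulein 100 pM, 1 for TLC-S 250 uM, 2 between the caerulein doses and 0 between caerulein 100 nM and TLC-S 250 uM. For the F test over 5 groups, 3 of 100 splits called as many as the real 3, the highest other also being 3. That share is under 0.05, but it rests on few splits and is imprecise. The splits also mixed libraries of different replicate numbers, between which 23 of 351 miRNAs differed (edgeR, adjusted p under 0.05). Chance was therefore not excluded. The share also holds for the full set of libraries only: the count fell to 1 without any 1 of 7 libraries, splits were not redrawn for those smaller sets, and 8 of 100 splits of the full set called at least 1.

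The low level of miR-3968 and miR-30b-5p at TLC-S 62.5 uM was weighed first. Over 3 other scalings the log2 difference nearest 0 was -1.69 (SE 0.38) for miR-3968 and -1.22 (SE 0.31) for miR-30b-5p. The call of miR-30b-5p ended there, with library totals (adjusted p = 0.0734, edgeR, with a range from 2.18e-05 to 0.416 over its alternatives). Library totals shifted the median log2 difference by 0.10 and the other scalings by less, too little to bring either value near 0. The test therefore shows only that the choice among these scalings was not the whole cause. Other miRNAs within 5 percentage points of hairpin GC had a median of 0.0066 (SD 0.41, 125 miRNAs) for miR-3968 and -0.037 (SD 0.49, 119 miRNAs) for miR-30b-5p. As a set they did not share the fall. This cannot exclude an effect of GC, because scaling holds the median of so many miRNAs near 0. The GC of the mature sequences was not examined. What stays open is an effect of GC content, reads of other small RNAs assigned to miR-3968, a mislabelled or separately handled group, and a response that is present at 62.5 uM and not at 250 uM. The values at hand can decide none of these.

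The higher miR-21a-3p at caerulein 100 nM was weighed second. Scaling alone would move both arms alike. With all libraries the log2 differences of the 3p and 5p arms lay 2.20 apart (SE 0.76, the arms taken as independent). The arm ratio changed by 1.82 (SE 0.83) and did not pass over 89 hairpins (adjusted p = 0.739, limma). These values go against scaling as the whole cause, but they include replicate 3 of caerulein 100 nM and do not exclude it. Dependence on 1 library fits the data: without replicate 3 the log2 difference was 1.00 (SE 0.89). Counting noise at low counts stays open for the same reason, because the fold from summed counts had a lower 95% bound of 3.86 with all libraries and 0.745 without that one. By the limit chosen afterwards, the values go against a general rise of minor arms as the whole cause. Over 89 hairpins the median was 0.062 (SD 0.57, 50 above 0 and 39 below), against 1.82 for miR-21. The interval of miR-21 reached down to 0.044, below that median, so a general rise of minor arms stays open.

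The lower acinar miRNAs at TLC-S 62.5 uM were weighed last. A lower share of acinar RNA in the preparation would raise the markers of other cell types alike. The lowest of 5 such scores, the endothelial one, changed by -2.57 times its SE and rests on both arms of 1 hairpin. That does not reach the limit of -4.60 that 5 scores with 4 degrees of freedom require. On the log2 scale the islet score changed by -0.10 (SE 0.17) and the leukocyte score by -0.025 (SE 0.17). The mesenchymal score changed by 0.11 (SE 0.097) and the erythrocyte score by 0.049 (SE 0.15). The explanation and a biological response to the bile acid therefore cannot be told apart, because the libraries are too few, and the group call itself ended with an estimated correlation.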

How the results depend on the processing

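Counts of calls moved with the processing, and the cause was not tested except where an alternative used fewer miRNAs or libraries. For TLC-S 62.5 uM against control the main count of 2 became 1 with library totals only, 5 with no low-count filter, 4 with DESeq2, 0 and 1 with limma on RPM at pseudocounts 1 and 10, and 0 with only the 2 groups, and ran from 0 to 3 over leave-outs (0 without replicate 1 or replicate 2). For TLC-S 250 uM against TLC-S 62.5 uM the main 4 became 2 with RLE, upper quartile, the 3 most abundant miRNAs left out, limma at pseudocount 10 or the highest precursor row, and 1 with a mean CPM of at least 10, and ran from 0 to 4 over leave-outs (0 without replicate 1 or replicate 2, and 1 without any single TLC-S 250 uM library). The F test moved from 3 to 10 with no filter, 1 at a mean CPM of at least 10 and 7 with DESeq2, and ran from 1 to 4 over leave-outs. DESeq2 gave 1 call in place of 0 for caerulein 100 nM against control and against TLC-S 250 uM. miR-3968 at TLC-S 62.5 uM was called in 26 of 31 alternatives (adjusted p from 8.07e-06 to 0.106) and miR-30b-5p in 21 of 31 (2.18e-05 to 0.416). miR-21a-3p at caerulein 100 nM was called in 0 of 29 (edgeR, DESeq2 and limma; adjusted p from 0.152 to 0.998), with log2 differences from 0.80 to 2.76, although the F test without a filter called it.

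The replicate numbers follow a code series in the labels, and each series holds each of the 5 groups once. The labels do not say whether a series is a single preparation. Same-numbered libraries deviated together only in part: 14 of 30 pairs correlated over 0.1 (mean 0.113, range -0.101 to 0.375), so the numbers were not taken as pairs. Further hints of a shared effect came from the data. Of 15 libraries, 11 correlated best with their own number, and 23 of 351 miRNAs differed between the series. The mean for other numbers was -0.056, which is not a further hint. Deviations from a group mean cancel over the numbers of that group, so this mean follows from that for the same number. If the series are blocks, the main model leaves their differences in its error. With the replicate block, TLC-S 62.5 uM against control had 5 calls, both main ones and miR-184-3p, miR-190a-5p and miR-335-5p, and the F test 6, all 3 main ones among them. The other counts of calls and the list calls did not change.

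List tests had 0 calls with an estimated correlation in place of 3, and from 0 to 5 without 1 replicate number. The correlation of the caerulein 100 nM and TLC-S 250 uM changes ran from 0.384 to 0.698 over these leave-outs (0.621 without replicate 2). Directions reversed for named miRNAs that had not passed. Over leave-outs, miR-148a-3p ran from -1.06 to 0.45 at caerulein 100 nM and from -0.93 to 0.66 at TLC-S 62.5 uM, turning positive without control replicate 3. Likewise let-7f-5p ran from -0.10 to 0.54 at caerulein 100 nM, and at TLC-S 62.5 uM miR-21a-5p from -0.62 to 0.019, miR-7a-5p from -0.55 to 0.14 and miR-19b-3p from -0.10 to 0.55. Between the TLC-S doses miR-1a-3p ran from -1.34 to 0.13, and between caerulein 100 nM and TLC-S 250 uM miR-7b-5p from -0.83 to 0.033. With library totals let-7i-5p at caerulein 100 pM was -0.021 and miR-192-5p between the caerulein doses 0.038, the latter 0.054 and 0.053 with limma at pseudocounts 1 and 10. miR-21a-3p had 1 to 136 counts per library, and whether depth or the spread between libraries set its error was not tested.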

Other observations

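All tests of hypotheses given here were chosen after related values had been seen. For the Mirg locus and the arm ratios, a p above the threshold was first read as excluding the hypothesis; that reading was withdrawn after the values were known.

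miR-6240, from a hairpin on chromosome 5 from 114851948 to 114852064 outside annotated genes, was at 38.2 ± 9.36 CPM with caerulein at 100 nM, 42.0 ± 12.8 at 100 pM and 33.5 ± 8.12 with TLC-S at 250 uM, against 14.0 ± 6.70 in control (SD, n = 3), and passed in none of these comparisons (edgeR). With TLC-S at 62.5 uM its level was 28.0 ± 22.5. Whether reads of other small RNAs were assigned to miR-6240, as left open for miR-3968, was not tested. Of 351 miRNAs, 23 differed between the 3 code series at an adjusted p under 0.05 (edgeR, F test in a model with group and series).

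Several miRNAs of the Mirg locus on chromosome 12 were among the lower values with caerulein, miR-154-5p at -3.02 for 100 pM among them. The hypothesis that this genomic cluster may change as a unit was tested among 32 clusters of at least 3 tested miRNAs in 6 comparisons (192 camera tests). It was not borne out: the smallest adjusted p of the locus against control was 0.190 with a preset and 0.956 with an estimated correlation, and 0 clusters passed in any comparison. Its median was below 0 at both doses (-0.28 and -0.18), so a change of the locus was neither shown nor excluded.

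A change in arm use specific to miR-21 was examined over 89 hairpins with both arms tested (limma on log2 arm ratios). The smallest adjusted p of miR-21 over the 4 treatments was 0.713, and 0 hairpins passed in any treatment. By p, miR-21 ranked 5 of 89 with caerulein at 100 nM, 11 at 100 pM, 2 with TLC-S at 250 uM and 85 at 62.5 uM, and its wide error (SE 0.83) leaves a change specific to it open.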
